A study of Mus musculus with 80 samples.

How the data were processed

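Left ventricular tissue of C57Bl/6J mice was profiled by RNA sequencing in 80 libraries. The libraries fall into 8 groups of 10, made of 4 conditions in each sex. These are the normal diet without irradiation (0 cGy, called sham below), the Western diet without irradiation (0 cGy), the normal diet with a mixed radiation field at 50 cGy, and the normal diet with gamma radiation at 100 cGy. A centigray (cGy) is a unit of absorbed radiation dose. The labels call the mixed field only "Mix" and do not name its components, and they give no age, time after exposure or hour of tissue collection. They do not say that the libraries come from separate animals, so the p-values measure the spread between these libraries, which may in part be technical.

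Per the labels' protocols, total RNA was purified on columns, mRNA was selected by its poly-A tail, and NEBNext Ultra II libraries were sequenced as paired ends on a NovaSeq-6000. Per the submitters' processing notes, FastQC 0.11.9 and STAR 2.7.8a were used with the GRCm39 (mm39) genome. The counting tool, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes, and of close gene copies such as the alpha and beta globin genes, may have been shared between them. The deposited table holds raw counts per Ensembl gene, whole numbers for 56941 genes in 80 columns, each named by a sample's title. Of these genes, 56323 matched the GENCODE vM39 annotation of GRCm39, from which symbols and coordinates were taken, and 41396 had at least 1 count. Total counts per library ran from 13484776 to 22143504, with a mean of 16518589. Mitochondrial genes took 23.6% ± 2.8 (SD, n = 80) of the counts.

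Library pairs of the same group were compared by a chi-square test of their counts. The smallest chi-square per degree of freedom in a group ran from 1.64, for female gamma replicates 8 and 9, to 14.1, so no pair was taken as copies of 1 library. Replicates 1 to 5 of each group carry title numbers 1 to 20 and replicates 6 to 10 carry title numbers 21 to 40. The labels do not say what separates these 2 runs of numbers, but many genes differed between them, so counts of genes are also given within each run (5 libraries per group). Same-numbered samples of different groups were not taken as paired. Female mixed field replicate 10 was the only library whose median correlation with its group lay over 5 median absolute deviations below the median over all 80.

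The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization. Genes with low counts were removed by filterByExpr on the groups, which left 15879 genes holding at least 99.82% of each library's counts. All 80 libraries entered 1 fit with 1 coefficient per group. Normalization factors ran from 0.868 to 1.14 and the common dispersion was 0.0415, a coefficient of variation of 20.4%. The 14 comparisons were each treatment against sham in males, in females and as the mean of the sexes, the 3 differences between the sexes in those effects, the mixed field against gamma radiation, and males against females among sham libraries. A gene was called when its Benjamini-Hochberg adjusted p was under 0.05. Fold changes are log2 values with their standard error (SE), which was taken as the fold change divided by the square root of the test's F value. Levels are CPM, counts scaled to a common library size, computed with TMM-adjusted library sizes, and given as mean ± SD. With 15879 genes, 794 are expected at an unadjusted p under 0.05 with no effect.

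The gene-wise test was run on counts simulated from the real means and library sizes for the Western diet in males (15879 genes). Of 50 genes each changed 1.25-, 1.5-, 2- and 3-fold it recovered 28, 78, 90 and 100%. There were 8 false calls, and 0 in an unchanged comparison. Yet 1 other split of real sham and gamma females gave 712 calls, so this 0 does not carry over.

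The genes named in the text were chosen by a rule. For each treatment effect these are the up to 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM, without predicted genes, receptor segments, Y-linked genes and Xist, together with up to 4 members of smallest p in each gene list. Where fewer than 5 genes were called, the 5 genes of smallest p are named too. For the other comparisons up to 8 called genes of largest change are named. Some genes that the rule selects are not reported here. The 36 lists cover fatty acid oxidation, cholesterol synthesis, fatty acid synthesis, glycolysis, the nuclear and the mitochondrially encoded respiratory chain, hypertrophy, sarcomere, ion channels, fibrosis, p53 targets, DNA repair, senescence, interferon response, MHC class II, macrophages, T and natural killer cells, B cells, neutrophils, endothelium, smooth muscle, fibroblasts, adipocytes, epicardium, atrial tissue, erythroid cells, skeletal muscle, Schwann cells, the circadian clock, immediate early genes, heat shock and unfolded protein response, NRF2 targets, glucocorticoid targets and hypoxia, cell cycle, complement, and Y-linked genes with Xist. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over the lists of a comparison, and again with an estimated correlation and with fry. The groups, tests, lists, naming rule and the first set of other settings were fixed before the data were examined.

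The settings fixed in advance were DESeq2 1.42.0, voom with quality weights, RLE size factors, no filter and a stricter filter on low counts, a term for the run of title numbers, surrogate variables (sva 3.50.0, which gave 5), a fit of only the groups compared, the fit without the library set apart, each run of title numbers alone, and, for the sexes among sham libraries, the title number as a replicate block. Chosen after the data had been seen were a run term for each sex, a fit without libraries over 10 CPM of Myl7 (by unadjusted library totals), the first 2 principal components of the clock list as terms, a fit without 4 libraries with unusual levels of named transcripts (male sham replicate 6, male gamma replicate 10, female mixed field replicate 5 and female gamma replicate 7), the log2 share of Rn18s-rs5 (a ribosomal RNA) with the run as terms for each sex, leaving out each library in turn, list tests within each run, splits of the samples drawn within each run, and a replicate block for the sex differences in effect. The clock components were computed over all 80 libraries, group differences included. They therefore remove part of any change in the clock list or in genes that follow it. Every column of the table was mapped to a sample and used.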

Results

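Gene expression was measured in 80 left ventricle libraries, 10 from each of 8 groups. The series asks about lasting effects of irradiation and of a high fat diet on this tissue. Group mean totals ran from 15388908 in male sham to 17625502 in gamma female libraries, so depth was similar across groups.

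The sex labels were checked first with transcripts from the sex chromosomes. Xist, the RNA that coats the inactive X chromosome (ENSMUSG00000086503, chromosome X, 102503972 to 102537573 on GRCm39), had 127 ± 19.3 CPM (SD, n = 10) in female sham libraries and 0.339 ± 0.196 CPM in male ones. Ddx3y, a Y-linked RNA helicase (ENSMUSG00000069045, chromosome Y, 1260715 to 1286663), had 48.3 ± 5.44 CPM in male sham libraries. Female gamma replicate 7 had 0.129 CPM of Xist.

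The Western diet was compared with the normal diet in unirradiated males. Adh1, an alcohol and retinol dehydrogenase (ENSMUSG00000074207, chromosome 3, 137966752 to 137996462), rose from 7.3 ± 1.33 to 13.5 ± 1.73 CPM (n = 10 each), a log2 change of 0.89 ± 0.16 (SE, adjusted p = 0.00192 by edgeR), and lay above the sham median in 10 of 10 libraries. Tspan4, a membrane tetraspanin placed in the clock list (ENSMUSG00000025511, chromosome 7, 141055138 to 141073340), rose from 22.7 ± 2.38 to 35.5 ± 6.05 CPM (0.65 ± 0.12, adjusted p = 0.00283, 9 of 10). The bicarbonate transporter Slc4a8 (0.89 ± 0.17), the monooxygenase Fmo2 (0.8 ± 0.18), the large scaffold protein Ahnak (0.66 ± 0.14) and the clock output factor Tef (0.58 ± 0.13) also rose. The magnesium transporter Slc41a3 fell (-0.71 ± 0.14), as did Leo1, a subunit of the elongation complex PAF1 (-0.61 ± 0.12). None of these 8 calls ended when any 1 library was left out.

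Other called genes in this comparison rested on fewer libraries. Fam107a (1.21 ± 0.28, adjusted p = 0.0207) had 0.148 without male Western replicate 7. The mitochondrial folate enzyme Mthfd1l (1.03 ± 0.23, adjusted p = 0.0199) had 0.0507 without male Western replicate 4. Prkag3, a regulatory subunit of AMP-activated kinase (-0.69 ± 0.16, adjusted p = 0.0199), had 0.0556 without male sham replicate 9. Bmp10, a growth factor of atrial muscle, was 4.62 lower on the log2 scale in the fit (-4.62 ± 0.77, adjusted p = 0.000947), but male sham replicate 6 alone held 149 CPM of it, and the adjusted p was 0.377 without that library. The collagen chaperone Serpinh1 fell from 204 ± 21.5 to 155 ± 20.7 CPM (-0.39 ± 0.09, adjusted p = 0.0307), and the endoplasmic reticulum foldase Pdia4 fell by 0.3 ± 0.07 (adjusted p = 0.0316). Their calls ended with any of 9 and of 11 libraries left out, and the highest adjusted p values were 0.0848 for Serpinh1 without male sham replicate 9 and 0.117 for Pdia4 without male Western replicate 2. Prkdc, a kinase of DNA end joining, was the 1 called member of the DNA repair list (0.46 ± 0.1, adjusted p = 0.0199), and its adjusted p was 0.0562, 0.0701 and 0.0518 without male Western replicates 2, 4 and 5.

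Of the 15879 genes tested, 63 were called in this comparison, 31 higher and 32 lower, and 2034 had an unadjusted p under 0.05. DESeq2 called 146 and voom 460. Within the runs of title numbers, 452 were called in the first and 0 by edgeR in the second (915 unadjusted). Without male sham replicates 1 to 4 singly the count was 31, 36, 37 and 36, without replicate 5 it was 195 and without replicate 9 it was 25. Without male Western replicates 1 to 5 singly it was 36, 26, 28, 20 and 30, and without replicate 6 it was 147. With 2 clock components as terms edgeR called 0 (1665 unadjusted). Myl7, the atrial myosin light chain, exceeded 10 CPM in 6 male sham and 5 male Western libraries and in no female one. Without them edgeR called 0 (700 unadjusted), but only second-run libraries of both groups remained, so this cannot be told from dropping the first run. Rn18s-rs5, a ribosomal RNA, took 0.178 to 0.419% of the counts in male Western replicates 1 to 5, against 0.293% in male sham replicate 5 and 1.58 to 1.95% in replicates 1 to 4. In the second run it took 1.46 to 2.32% in Western and 1.5 to 3.22% in sham males. With the log2 of this share and the run as terms for each sex 20 genes were called, 16 of them among the 63. Over the 63 genes the median absolute log2 change was 0.48 (median SE 0.12). It was 0.64 (0.15) and 0.34 (0.14) within the runs, 0.27 (0.11) with the clock components, 0.37 (0.16) without libraries over 10 CPM of Myl7 and 0.39 (0.11) with the terms for Rn18s-rs5 and the run.

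The circadian clock list had 21 measured members, of which Tspan4 and Tef rose and Nr1d1 fell in males on the Western diet. Nr1d1, the clock repressor REV-ERB alpha, went from 159 ± 29.9 to 106 ± 15.2 CPM (-0.58 ± 0.13, adjusted p = 0.0199), and its adjusted p was 0.0602, 0.0508 and 0.0507 without male sham replicate 2 and male Western replicates 2 and 4. Adjusted over the list alone, 8 members were higher and 2 lower, and 15 of 21 had a positive change with a median of 0.28. Bmal1, the transcription factor that drives the clock (ENSMUSG00000055116, chromosome 7, 112806152 to 112914735), had 7.42 ± 2.09 CPM in sham and 3.09 ± 2.5 CPM in Western males and did not pass (adjusted p = 0.0657). The list's change was called upward by camera (adjusted p = 0.00502, and 0.64 with an estimated correlation). Within runs the values were 0.224 and 8.06e-06. The fatty acid oxidation list of 32 genes, 2 of them positive, had 0 called members (0 adjusted over the list alone) and a median of -0.09, called downward (adjusted p = 0.0266, and 0.955 with an estimated correlation). Its within-run values were 0.00542 and 0.432. The example Acot2, a mitochondrial acyl-CoA thioesterase, had -0.33 ± 0.12 (adjusted p = 0.186).

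**Figure D1:**
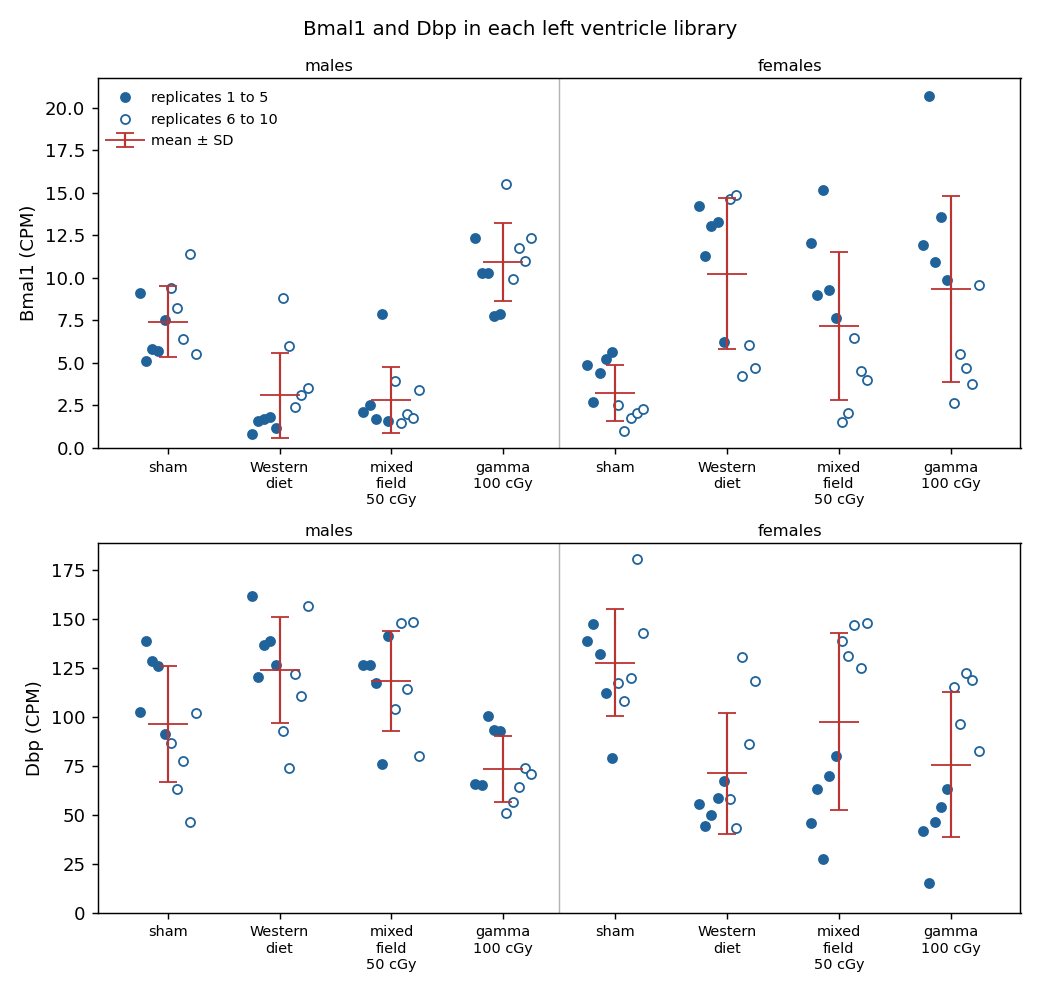
Levels of Bmal1 and Dbp (CPM) in each library, by group; points are single libraries, marked by their run of title numbers, and bars are means with SD. Bmal1 averaged 7.42 CPM in male sham and 3.09 CPM in male Western libraries, against 3.24 and 10.3 CPM in females.

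In females on the Western diet, Bmal1 rose from 3.24 ± 1.64 to 10.3 ± 4.41 CPM (n = 10 each), a log2 change of 1.66 ± 0.33 (adjusted p = 0.0199), and was above the sham median in 10 of 10 libraries. Tspan4 fell from 30.9 ± 7.33 to 19.6 ± 3.31 CPM (-0.65 ± 0.12, adjusted p = 0.00884), and Ypel2 rose from 16.1 ± 2.95 to 22.9 ± 2.79 CPM (0.51 ± 0.1, adjusted p = 0.0107). These were the 3 genes called, 2 higher and 1 lower, and 1174 had an unadjusted p under 0.05. Npas2, which pairs with Bmal1, had 1.87 ± 0.659 CPM in sham and 4.46 ± 2.15 CPM in Western females (adjusted p = 0.0621) and did not pass, nor did Efcc1 (0.98 ± 0.22, adjusted p = 0.0925). DESeq2 called 8 and voom called 0, with 1138 at an unadjusted p under 0.05. Within the runs 1 and 2 were called, with a run term for each sex 28, the 3 among them, and with the clock components 0 by edgeR (943 unadjusted). The median absolute change of the 3 genes was 0.65 (SE 0.12), 0.58 (0.12) with voom and 0.24 (0.1) with the clock components. Without female sham replicate 9 edgeR called 0 (803 unadjusted), and the adjusted p was 0.0701 for Tspan4, 0.0738 for Ypel2 and 0.075 for Bmal1. Without female Western replicates 5, 8 and 9 singly, 5, 11 and 5 were called. The Bmal1 call also ended without female sham replicates 6, 7, 8 and 10 (0.0614, 0.0522, 0.0783 and 0.0527) and female Western replicates 1, 3, 4, 6 and 7 (0.0626, 0.0529, 0.0553, 0.0661 and 0.0677).

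The clock list moved the other way in females on the Western diet. Of 21 members, Bmal1 rose and Tspan4 fell, 4 were higher and 11 lower adjusted over the list alone, and 6 were positive with a median of -0.34. Dbp, a clock output factor, had 128 ± 27.4 CPM in sham and 71.2 ± 30.8 CPM in Western females. The downward call (adjusted p = 5.21e-06) held with an estimated correlation (0.0464) and in both runs (0.000388 and 1.55e-05). The macrophage list was called downward (4 of 27 positive, adjusted p = 0.000251, and 0.995 with an estimated correlation), with 0.864 and 1.62e-10 within runs. It had 0 called members, also over the list alone. Its examples Adgre1, the macrophage antigen F4/80, and Cd68 had -1.01 ± 0.32 and -0.37 ± 0.15. Heat shock genes (5 of 31 positive, adjusted p = 0.0025, and 0.76 with an estimated correlation), glycolysis (2 of 23, 0.00223, and 0.76) and fatty acid oxidation (4 of 32, 0.00981, and 0.995) were called downward. The B cell list was called upward (12 of 16, 0.0348, and 0.995). These 4 lists had 0 called members, also adjusted over the list alone. Their within-run values were 0.0294 and 0.0262, 0.00312 and 0.0479, 2.71e-05 and 0.962, and 0.281 and 0.0918.

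The difference between the sexes in the diet effect was tested directly as an interaction. Bmal1 (-2.9 ± 0.47), Tspan4 (1.3 ± 0.17), Per2, a repressor of the clock (1.75 ± 0.32), Npas2 (-1.84 ± 0.38), Tef (1.11 ± 0.18) and Hlf (1.46 ± 0.31) differed, with adjusted p from 6.27e-07 for Tspan4 to 0.00654. Values are the male minus the female log2 change. Spon2, an extracellular matrix protein, differed by -3.17 ± 0.52 (adjusted p = 7.82e-05), Mthfd1l by 1.96 ± 0.33 (adjusted p = 0.000118) and Tmem171 by -1.5 ± 0.27 (adjusted p = 0.000702). None of these 9 calls ended with any 1 library left out. Tnfrsf12a (-1.53 ± 0.37, adjusted p = 0.0297) lost its call without any of 11 libraries, up to 0.0956 without female Western replicate 7, and Bmp10 (-4.96 ± 1.16, adjusted p = 0.0228) had 0.868 without male sham replicate 6.

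Over all genes, 71 were called for this difference, 31 higher and 40 lower, with 1468 at an unadjusted p under 0.05. With the clock components as terms 1 was called, and the median absolute change of the 71 went from 0.91 (SE 0.19) to 0.31 (0.2), with 61 in the same direction. Without libraries over 10 CPM of Myl7 1 was also called, but there the change stayed at 0.88 while the SE grew to 0.25, with 70 in the same direction. DESeq2 called 110 and voom 140, and 22 and 26 were called within the runs. Without male Western replicate 6 the count was 111, and it was 42, 40 and 46 without female sham replicates 6 and 8 and female Western replicate 7. The clock list had 7 members higher and 2 lower (13 and 5 adjusted over the list alone), 16 of 21 positive, and was called upward (adjusted p = 1.59e-08), also with an estimated correlation (adjusted p = 0.00596) and within both runs (0.000301 and 3.15e-08). The called members Per3, Cry2 and Ciart lost their calls with any of 24, 25 and 24 of 40 libraries left out, up to 0.0919 and 0.0893 for Per3 and Ciart without female Western replicate 7 and 0.102 for Cry2 without female sham replicate 7. The macrophage list differed too (25 of 27 positive, 0 members called, 0 adjusted over the list alone, adjusted p = 0.000141, and 0.967 with an estimated correlation), with 0.0252 and 0.000644 within runs.

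**Figure D2:**
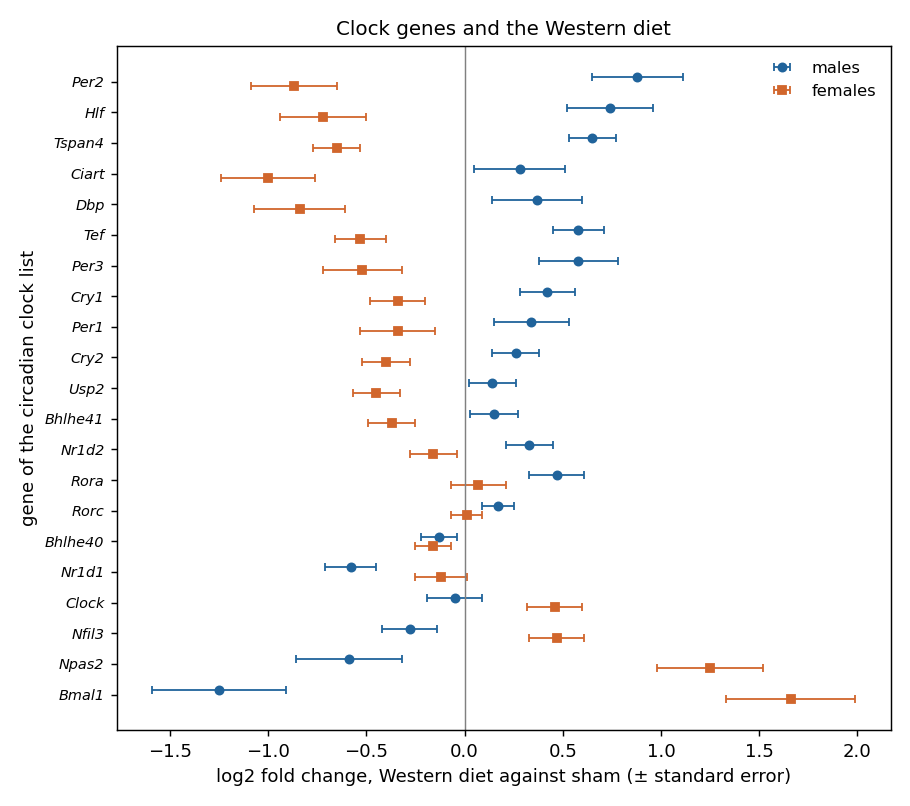
Log2 fold change of clock genes on the Western diet in males and in females, with SE as error bars. Tspan4 was 0.65 in males and -0.65 in females, and Bmal1 was 1.66 in females.

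In the mean of the sexes, the Western diet left edgeR with 0 called genes and 1806 at an unadjusted p under 0.05. DESeq2 and voom also called 0, with 1860 and 2508 at that level, and 92 and 0 were called within the runs (478 unadjusted in the second). The genes of smallest p, Hs3st5 (0.48 ± 0.11), Ino80d (0.38 ± 0.09), Tuba4a (-0.36 ± 0.09), Ttc39b (0.3 ± 0.07) and Dennd5b (0.35 ± 0.09), failed with an adjusted p of 0.23. Fatty acid oxidation (3 of 32 positive, adjusted p = 0.000196, and 0.961 with an estimated correlation), heat shock (6 of 31, 0.000196, and 0.56) and glycolysis (3 of 23, 0.00175, and 0.961) were called downward. They had 0 called members, and adjusted over the list alone 0, 1 and 0. The within-run values were 4.6e-06 and 0.468, 0.0262 and 0.000329, and 4.6e-06 and 0.949.

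The mixed field at 50 cGy was compared with sham in males. Glul, glutamine synthetase (ENSMUSG00000026473, chromosome 1, 153775690 to 153785469), rose from 345 ± 29.4 to 469 ± 91.4 CPM (n = 10 each), a log2 change of 0.44 ± 0.08 (adjusted p = 0.0051), and was above the sham median in 9 of 10 libraries. St6galnac3, a sialyltransferase, fell from 5.52 ± 1.16 to 3.1 ± 0.416 CPM (-0.83 ± 0.15, adjusted p = 0.00174, 10 of 10). Both calls held without any 1 library. Slc41a3 fell by 0.72 ± 0.14 on the log2 scale (adjusted p = 0.0142, and 0.0523 without male sham replicate 1). Rhobtb1 rose by 0.69 ± 0.14 (adjusted p = 0.0208), which became 0.0539 and 0.0645 without male mixed field replicate 4 and male sham replicate 6. Bmp10 again had a call (-4.29 ± 0.75) that rested on male sham replicate 6, with an adjusted p of 0.408 without it.

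In this comparison 11 genes were called, 6 higher and 5 lower, and 1297 had an unadjusted p under 0.05. The others were Zfp1003, Shld1, Acyp1 and Rnf114, which were higher by 0.73, 0.61, 0.55 and 0.28, and Nr1d1 and Leo1, which were lower (-0.6 and -0.53). Their calls ended without any of 6, 10, 12, 4, 7 and 9 libraries, with adjusted p up to 0.0851 (male mixed field replicate 10), 0.104 (male mixed field replicate 1), 0.158 (male mixed field replicate 3), 0.0698 (male mixed field replicate 3), 0.102 (male sham replicate 2) and 0.0698 (male mixed field replicate 3). DESeq2 called 23, 16 higher and 7 lower. Within the runs 17 and 0 were called, with 1053 at an unadjusted p under 0.05 in the second. Without male mixed field replicates 1, 3, 4, 5, 6 and 8 singly the count was 7, 6, 6, 28, 17 and 26, and without male sham replicates 1, 3 and 6 it was 4, 7 and 6. Male mixed field replicate 8 held 627 CPM of Myl7, and edgeR called 0 without libraries over 10 CPM of it (1208 unadjusted) and 0 with the clock components as terms (1213 unadjusted). The median absolute change of the 11 genes was 0.61 (SE 0.13), and 0.59 without those libraries, where the SE grew to 0.19. It was 0.32 (0.13) with the clock components, and 0.67 (0.17) and 0.5 (0.17) within the runs. Rn18s-rs5 took 0.163 to 0.536% of the counts in male mixed field replicates 1 to 4, 1.63% in replicate 5 and 1.37 to 2.73% in the second run. With its share and the run as terms for each sex 20 genes were called, 7 of them among the 11.

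Among lists in males after the mixed field, the interferon response had 45 of 49 members positive and a median of 0.23. It had 0 called members, and 5 higher adjusted over the list alone. Ifit3b, an interferon-induced gene, had 0.61 ± 0.18 (adjusted p = 0.214) and Gbp6, an interferon-induced GTPase, 0.64 ± 0.2 (adjusted p = 0.272). The upward call (adjusted p = 5.17e-07) was lost with an estimated correlation (adjusted p = 0.643), and its within-run values were 6.56e-10 and 0.373. The fibrosis list was called downward (14 of 48 positive, adjusted p = 1.23e-07), with Col15a1 at -0.68 ± 0.18 (adjusted p = 0.158), and the fibroblast list as well (2 of 20, adjusted p = 0.0034). Fatty acid oxidation (6 of 32, adjusted p = 0.00923) and atrial markers (5 of 18, adjusted p = 0.00819) were called downward, while the clock (15 of 21, adjusted p = 0.00682) and neutrophil markers (5 of 5, adjusted p = 0.0135) were called upward. With an estimated correlation the adjusted p was 0.938 for fatty acid oxidation and 0.643 for the others. Adjusted over the list alone, fibrosis had 1 lower, fibroblasts 0, fatty acid oxidation 1 lower, atrial markers 2 lower, the clock 6 higher and 2 lower, and neutrophils 4 higher. Only Bmp10 and Nr1d1 of these lists were called over all genes. Within runs the values were 0.503 and 1.12e-14 for fibrosis, 0.503 and 2.49e-05 for fibroblasts, 5.06e-05 and 0.644 for fatty acid oxidation, 0.503 and 6.45e-05 for the clock and 0.503 and 0.00333 for neutrophils. Atrial markers were downward in the first (2.92e-12) and upward in the second (0.443).

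In females after the mixed field, edgeR called 0 genes and gave 1027 at an unadjusted p under 0.05. DESeq2 and voom also called 0, with 1058 and 1735. Without female mixed field replicate 10, the library set apart, edgeR gave 0 and 641. Among the genes of smallest p, Tent5c (1.56 ± 0.37, adjusted p = 0.483, above the sham median in 10 of 10), Cops8 (-0.23 ± 0.06, adjusted p = 0.483) and the uncharacterised 6430548M08Rik (0.37 ± 0.1, adjusted p = 0.652) failed. Hba-a2, an alpha globin, had 34.8 ± 35.3 CPM against 10.3 ± 5.19 CPM (1.74 ± 0.46, adjusted p = 0.652). Within the runs of title numbers 39 and 4 genes were called. Female mixed field replicate 5 had the highest level of Alas2, the first enzyme of heme synthesis in red cells, at 114 CPM.

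The erythroid list was called upward in these females, with 9 of 10 members positive and a median of 1.67. It had 0 called members and 8 higher adjusted over the list alone, and its adjusted p of 2.06e-07 became 0.342 with an estimated correlation (0.0002 and 0.00931 within runs). It was 0.000707 without the 4 libraries with unusual transcripts, female mixed field replicate 5 among them. Interferon response (41 of 49 positive, adjusted p = 0.000291), glucocorticoid targets and hypoxia (18 of 20, adjusted p = 0.000367), hypertrophy (17 of 19, adjusted p = 0.00322) and neutrophils (5 of 5, adjusted p = 0.0194) were also upward. With an estimated correlation these had adjusted p of 0.857, 0.535, 0.755 and 0.755. Fatty acid oxidation (3 of 32, adjusted p = 0.000226), the clock (4 of 21, adjusted p = 0.00118), cholesterol synthesis (7 of 24, adjusted p = 0.0116) and the nuclear respiratory chain (21 of 56, adjusted p = 0.0296) were downward, with 0.816, 0.342, 0.352 and 0.876 with an estimated correlation. None of these 8 lists had a called member, and adjusted over the list alone the clock had 1 higher and the others 0. In the first run each of the 8 had an adjusted p of 0.013 or less. In the second the values were 0.994 for interferon response, 0.436 for glucocorticoid targets, 0.994 for hypertrophy, 0.788 for neutrophils, 0.666 for the clock and 0.584 for cholesterol synthesis. In that run fatty acid oxidation and the respiratory chain were upward (0.614 and 0.00116).

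The sexes differed in their response to the mixed field in 5 genes, 1 higher and 4 lower. Spon2 (-2.65 ± 0.51), Bmal1 (-2.51 ± 0.48) and Tspan4 (0.86 ± 0.17) each had an adjusted p of 0.0124 and kept it under 0.05 without any 1 library. St6galnac3 (-1.01 ± 0.21, adjusted p = 0.019) had 0.0518 without female mixed field replicate 10. Leo1 (-0.79 ± 0.16, adjusted p = 0.0246) lost its call without any of 12 libraries, up to 0.0859 without female mixed field replicate 2. At an unadjusted p under 0.05 there were 1429 genes, DESeq2 called 11 and voom 38, and 9 and 0 were called within the runs (1801 unadjusted in the second). The median absolute change of the 5 genes was 1.01 (SE 0.21), and 0.94 (0.32) and 1.19 (0.26) within the runs, with all 5 in the same direction in each. With the clock components as terms edgeR called 0 (901 unadjusted) and the change was 0.5 (0.23). The count was 8, 9, 11, 12 and 3 without male mixed field replicates 4 and 5 and female mixed field replicates 6, 7 and 10.

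Of lists in this difference, the clock was upward (16 of 21 positive, adjusted p = 4.02e-05, and 0.15 with an estimated correlation), with Tspan4 up and Bmal1 down among all genes and 10 higher and 3 lower adjusted over the list alone. The erythroid list was downward (1 of 10 positive, adjusted p = 4.02e-05) with 6 lower adjusted over the list alone (adjusted p = 0.00313 without the 4 libraries), and fibrosis too (14 of 48, adjusted p = 6.07e-06) with 1. Endothelial markers (6 of 22, adjusted p = 0.0474) were downward and NRF2 targets (22 of 26, adjusted p = 0.0367) upward, with 0 adjusted over the list alone. These 4 lists had an adjusted p of 0.88 with an estimated correlation and 0 called members. Within runs the values were 0.000403 and 0.0124 for the clock, 0.000862 and 0.0238 for the erythroid list, 2.58e-07 and 0.0974 for fibrosis, 0.229 and 0.0636 for endothelial markers, and 0.0018 and 0.57 for NRF2 targets.

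As the mean of the sexes, the mixed field gave 0 calls by edgeR, with 905 genes at an unadjusted p under 0.05. DESeq2 called 0 (938 unadjusted) and voom 4, and 48 and 0 were called within the runs (1547 unadjusted in the second). Among the genes of smallest p, Zfp1003 (0.49 ± 0.11), Glul (0.26 ± 0.06) and Dcaf13 (-0.21 ± 0.05) failed with an adjusted p of 0.144, and Gbp6 (0.6 ± 0.14) with 0.162. Without male mixed field replicates 5 and 9 singly 4 and 1 genes were called. The interferon response was upward in 47 of 49 members (adjusted p = 2.83e-12, and 0.426 with an estimated correlation), with 2 higher adjusted over the list alone and 1.65e-14 and 0.494 within runs. The neutrophil list was upward (5 of 5, adjusted p = 0.000108, 4 higher adjusted over the list alone), as were glucocorticoid targets (16 of 20, 0.000653), erythroid markers (10 of 10, 0.00635), T cell markers (13 of 14, 0.0127) and hypertrophy (13 of 19, 0.0438, 1 higher adjusted over the list alone). Fatty acid oxidation (5 of 32, 2.29e-07, 1 lower adjusted over the list alone), fibroblasts (6 of 20, 0.000129), cholesterol synthesis (8 of 24, 0.00842) and fatty acid synthesis (8 of 18, 0.0327, 1 lower adjusted over the list alone) were downward. With an estimated correlation the adjusted p of these 9 lists was 0.426, but 0.73 for erythroid markers, 0.765 for T cells and 0.899 for hypertrophy. Without the 4 libraries the erythroid list had 0.14.

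For these means of the sexes the values within the runs were as follows, with no test of a difference between the runs. Neutrophil markers had 0.0175 and 0.0278, glucocorticoid targets 0.000694 and 0.338, erythroid markers 0.0756 and 0.218, T cell markers 0.00176 and 0.885, fibroblasts 0.894 and 2.26e-07, and cholesterol synthesis 0.0258 and 0.338. Fatty acid oxidation was downward in the first (1.53e-14) and upward in the second (0.867), hypertrophy upward (0.000694) and then downward (0.772), and fatty acid synthesis upward (0.914) and then downward (0.00349). Fibrosis was called downward in the mean of the sexes (adjusted p = 0.00595, and 0.932 with an estimated correlation, 0 adjusted over the list alone) with 23 of 48 members positive, a median of -0.01 and a mean of 0. It was upward in the first run (0.00131) and downward in the second (3.91e-15).

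Gamma radiation at 100 cGy was compared with sham in males. The largest rises were in lymphocyte genes, led by Ms4a4b, a T cell membrane protein (ENSMUSG00000056290, chromosome 19, 11412557 to 11444419), at 7.38 ± 20.8 against 0.383 ± 0.263 CPM (n = 10 each), a log2 change of 4.26 ± 0.69 (adjusted p = 0.000377). The cytokine receptors Il7r (3.28 ± 0.56, adjusted p = 0.000614) and Il2rb (3.16 ± 0.55, adjusted p = 0.000744) followed, with Ly6c2 (3.11), Gimap3 (2.83), Il18r1 (2.54), the T cell factor Tcf7 (2.51), Grap2 (2.1) and Itgb7 (1.66). These values came mainly from male gamma replicate 10, which held 66.6 CPM of Ms4a4b, and without it the adjusted p of Ms4a4b, Il7r and Il2rb was 0.998. Itgb7 also lost its call without male sham replicates 4, 5 and 10 (0.0514, 0.0678 and 0.0548). Bmp10 was lower (-4.61 ± 0.76), with 0.783 without male sham replicate 6.

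In all, 28 genes were called in this comparison, 27 higher and 1 lower, and 863 had an unadjusted p under 0.05. Without male gamma replicate 10 the count was 1. Without it and male sham replicate 6 (with 2 female libraries) edgeR called 0 (612 unadjusted). The count was 0 without libraries over 10 CPM of Myl7 (418 unadjusted), which left only second-run males. It was 18 and 18 without male sham replicates 3 and 5, and 48, 43, 46, 43 and 47 without male gamma replicates 1, 4, 6, 7 and 9. DESeq2 called 12 and voom 0 (1352 unadjusted). Within the runs edgeR called 0 and 7, with 894 at an unadjusted p under 0.05 in the first. With the share of Rn18s-rs5 and the run as terms for each sex edgeR called 0 (791 unadjusted). The median absolute change of the 28 genes was 2.51 (SE 0.54), and 2.18 (0.56) with these terms, with all 28 in the same direction. It was 0.51 (0.37) without the 4 libraries, 0.51 (0.59) without libraries over 10 CPM of Myl7, male gamma replicate 10 among them, 0.76 (0.42) with voom, and 0.65 (0.57) and 3.27 (0.8) within the runs.

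**Figure D3:**
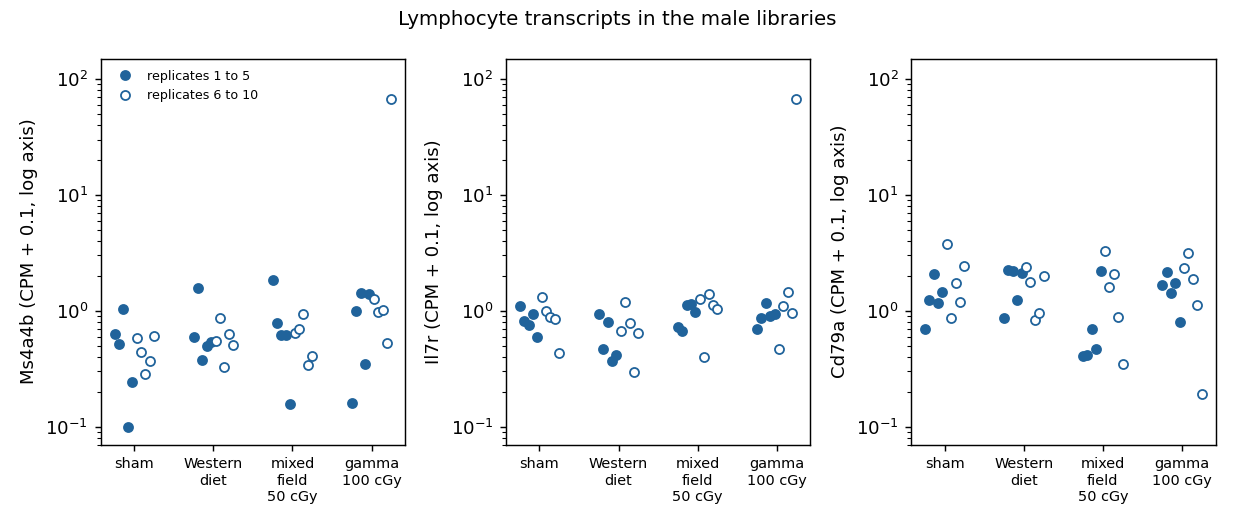
Lymphocyte transcripts Ms4a4b and Il7r and the B cell transcript Cd79a (CPM plus 0.1, log axes) in each male library, by group; points are single libraries. Male gamma replicate 10 lies at 66.6 CPM of Ms4a4b, far above the other libraries.

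Immune lists were upward in males after gamma radiation. Of the T and natural killer cell list all 14 were positive and 7 rose (12 adjusted over the list alone). Without male gamma replicate 10 the 7 calls ended. The interferon list had 47 of 49 positive with a median of 0.29, and the MHC class II list, which presents antigen to T cells, 9 of 9 with a median of 0.41. In these no member was called, and 11 and 3 were higher adjusted over the list alone. Igtp, an interferon-induced GTPase, had 0.68 ± 0.2 (adjusted p = 0.216), and Ciita, the master regulator of class II genes, 0.66 ± 0.21 (adjusted p = 0.284). The adjusted p was 4.19e-09 for T cells, 3.23e-13 for interferon and 2.43e-07 for class II, and with an estimated correlation 0.153, 0.518 and 0.153. Within runs they were 0.0223 and 9.66e-09, 1.87e-06 and 1.17e-09, and 0.0038 and 5.18e-06. Without the 4 libraries, male gamma replicate 10 among them, they were 0.00029, 2.19e-09 and 2.19e-09.

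Other lists in males after gamma radiation had few or no called members. Fatty acid oxidation was downward (1 of 32 positive, median -0.11, adjusted p = 2.43e-07, and 0.648 with an estimated correlation), with 7.35e-07 and 0.00359 within runs. Acot2 had -0.31 ± 0.12 (adjusted p = 0.649). The nuclear respiratory chain (10 of 56, 0.00503), glycolysis (2 of 23, 0.0432) and the mitochondrially encoded chain (1 of 13, 0.045) were downward, with 0.909, 0.736 and 0.909 with an estimated correlation. Macrophages (26 of 27, 0.000475), immediate early genes (17 of 25, 0.000936), complement (12 of 14, 0.00256) and epicardial markers (6 of 6, 0.00405) were upward, with 0.736, 0.736, 0.734 and 0.195. Adjusted over the list alone, 1 epicardial gene was higher and 0 members of the other 7 passed. Within runs these had 6.78e-05 and 0.693 (nuclear chain), 3.09e-05 and 0.304 (macrophages), 0.0126 and 0.0518 (immediate early genes), 0.0788 and 0.00129 (complement), and 0.0544 and 0.0193 (epicardial). Glycolysis and the mitochondrially encoded chain were downward in the first run (3.09e-05 and 0.000599) and upward in the second (0.693 and 0.999).

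In females after gamma radiation edgeR called 0 genes, with 1643 at an unadjusted p under 0.05. DESeq2 and voom called 3 each, and 6 and 0 were called within the runs (843 unadjusted in the second). Mamstr, a coactivator of muscle genes, had 6.3 ± 0.84 against 8.99 ± 1.47 CPM (-0.52 ± 0.11, adjusted p = 0.126, below the sham median in 10 of 10). Bmal1 had 9.33 ± 5.46 against 3.24 ± 1.64 CPM (1.52 ± 0.33, adjusted p = 0.142, 10 of 10), and Lvrn, an aminopeptidase, 1.53 ± 0.593 against 0.646 ± 0.374 CPM (1.26 ± 0.28, adjusted p = 0.148). Mlf1 (-0.49 ± 0.12) and Or5m3b (0.71 ± 0.17) failed too. Without female sham replicate 7 the count was 1 and without female gamma replicate 6 it was 2.

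The nuclear respiratory chain was downward in these females, with 1 of 56 members positive, a median of -0.15 and an adjusted p of 2.54e-11 (0.981 with an estimated correlation). It had 0.00195 and 1.35e-16 within runs, and its example Ndufb10 had -0.25 ± 0.1 (adjusted p = 0.405). The cell cycle was downward (1 of 30 positive, median -0.54, adjusted p = 4.94e-07, and 0.981), with 0.0794 and 1.8e-10 within runs and the replication helicase subunit Mcm5 at -0.71 ± 0.19 (adjusted p = 0.325). Interferon response was downward (8 of 49, 0.000558), with 8.23e-05 and 0.214, and glycolysis too (5 of 23, 0.00427), with 0.115 and 0.00341. Glucocorticoid targets and hypoxia were upward (18 of 20, 6.29e-05), with 8.73e-07 and 0.214. Its examples were the cell cycle inhibitor Cdkn1a (0.9 ± 0.28, adjusted p = 0.363) and Pdk4 (0.83 ± 0.29, adjusted p = 0.386), a kinase that restrains glucose oxidation. These also had 0.981 with an estimated correlation. No member of the 5 lists was called, and adjusted over the list alone glucocorticoid targets had 4 higher, the cell cycle 1 lower and the others 0.

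The difference between the sexes in the gamma effect had 0 calls by edgeR and voom, with 854 and 853 genes at an unadjusted p under 0.05, and 2 by DESeq2. Within the runs 0 and 0 were called, with 768 and 733. Limd2 (1.31 ± 0.27) and the leukocyte protein Spn (3.06 ± 0.64) had an adjusted p of 0.0705, and H2-DMa, which loads class II molecules (0.89 ± 0.21), Il2rb (3.18 ± 0.79) and Bmp10 (-4.73 ± 1.17) had 0.252. Il2rb rose by 3.16 in males, and by 0.12 without male gamma replicate 10. Bmp10 differed by 0.69 without the 4 libraries, male sham replicate 6 among them. The count of calls was 2 without male gamma replicates 6, 8 and 9 or female sham replicates 5, 6, 7 and 8 singly, and 1 without female gamma replicate 7. By list, the effect on the interferon response was higher in males than in females in 48 of 49 members (median difference 0.46). Its adjusted p was 8.32e-18 (0.507 with an estimated correlation), with 13 higher adjusted over the list alone. Its within-run values were 1.58e-13 and 4.08e-08. The class II list had 9 of 9 positive (adjusted p = 4.38e-07, and 0.295), 2 higher adjusted over the list alone, and 0.000561 and 0.000133 within runs.

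Other lists differed between the sexes after gamma radiation. Immediate early genes (24 of 25 positive, adjusted p = 1.2e-05), macrophages (23 of 27, 2.52e-05), T cells (14 of 14, 2.93e-05), the nuclear respiratory chain (51 of 56, 0.000451) and the cell cycle (26 of 30, 0.00519) were higher in males, with 0.533, 0.653, 0.533, 0.953 and 0.953 with an estimated correlation. Fatty acid oxidation (5 of 32, 2.52e-05), the mitochondrially encoded chain (1 of 13, 0.000451) and glucocorticoid targets (5 of 20, 0.000739) were lower, with 0.653, 0.653 and 0.533. No member was called, and adjusted over the list alone T cells had 11 higher, fatty acid oxidation 2 lower, glucocorticoid targets 3 lower and the others 0. The T cell values rest in part on male gamma replicate 10. Without it Il2rb, Il7r and Tcf7 changed in males by 0.12, 0.15 and -0.01, against 3.16, 3.28 and 2.51. Without the 4 libraries the T cell list had an adjusted p of 0.00474. Within runs immediate early genes had 0.000137 and 0.00843, macrophages 0.000137 and 0.0136, T cells 0.0117 and 0.00306, the cell cycle 0.0299 and 0.047, fatty acid oxidation 0.01 and 0.000148, and glucocorticoid targets 4.51e-07 and 0.712. The nuclear chain was lower in the first run (0.901) and higher in the second (3.34e-08), and the mitochondrially encoded chain lower (8.38e-13) and then higher (0.483).

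As the mean of the sexes, gamma radiation gave 0 calls by edgeR, with 1732 genes at an unadjusted p under 0.05. DESeq2 called 0 (1761 unadjusted) and voom 42, and 7 and 0 were called within the runs (763 unadjusted in the second). Bmal1 (1.04 ± 0.23), Ms4a4b (2.34 ± 0.5), Ly6c2 (2.01 ± 0.45) and Hdgfl3 (0.26 ± 0.06) failed with an adjusted p of 0.119, and Il7r (1.81 ± 0.42) with 0.123. Without male gamma replicate 10 the changes in males were 1.05 for Ms4a4b, 0.21 for Ly6c2 and 0.15 for Il7r. The nuclear respiratory chain was downward in both runs (1 of 56 positive, adjusted p = 2.04e-10, 1.33e-05 and 2.17e-10 within runs). The cell cycle (2 of 30, 3.49e-06; 0.484 and 1.45e-12), glycolysis (3 of 23, 0.00135; 0.000378 and 0.0911), the clock (7 of 21, 0.0329; 0.00288 and 0.581) and fatty acid oxidation (5 of 32, 0.0329; 0.000216 and 0.841) were downward. T cells (14 of 14, 0.00172; 0.498 and 9.01e-06), glucocorticoid targets (15 of 20, 0.00649; 0.0122 and 0.0767) and complement (13 of 14, 0.00968; 0.152 and 0.0011) were upward. With an estimated correlation the adjusted p was 0.719, and 0.967 for fatty acid oxidation. No member was called, and adjusted over the list alone T cells had 9 higher, the clock 3 higher and 11 lower, glucocorticoid targets 4 higher, complement 1 higher and the others 0. Without the 4 libraries the T cell list had an adjusted p of 0.149.

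The mixed field and gamma radiation, given at different doses, were compared directly as the mean of the sexes. Bmal1 was lower after the mixed field (-1.15 ± 0.23), as was Slc41a3 (-0.52 ± 0.1), and Cys1, a protein of the primary cilium, was higher (0.64 ± 0.13). Each had an adjusted p of 0.02. Per2 (0.72 ± 0.16) and Tef (0.4 ± 0.09) failed with 0.068. These 3 were the genes called, 1 higher and 2 lower, with 1649 at an unadjusted p under 0.05. DESeq2 called 7, 5 higher and 2 lower, and voom 0, with 1073 at an unadjusted p under 0.05. Within the runs 4 and 24 were called. With the clock components as terms 33 were called, none of them among the 3, and without libraries over 10 CPM of Myl7 edgeR called 0 (1043 unadjusted). The median absolute change of the 3 genes was 0.64 (SE 0.13), 0.33 (0.11) with the clock components, 0.67 without those libraries, where the SE grew to 0.17, and 0.54 (0.13) with voom. Without female mixed field replicate 10 the count at an unadjusted p under 0.05 was 1095. Without male mixed field replicates 3, 4, 5 and 8 singly the count was 5, 7, 1 and 0 (1654 unadjusted for the last), without female mixed field replicates 1, 2, 3, 4, 6, 7 and 10 it was 5, 5, 7, 6, 0, 0 and 1 (1624 and 1718 unadjusted for replicates 6 and 7), and without female gamma replicates 1, 2 and 6 it was 0, 0 and 8 (1492 and 1530 unadjusted for replicates 1 and 2).

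The lists most tied to radiation damage had no call in any of 12 comparisons. The p53 target list of 34 genes had a smallest adjusted p of 0.465, in females on the Western diet, DNA repair (38 genes) 0.281, in males after gamma radiation, and senescence (26 genes) 0.243, in females after the mixed field. Adjusted over the list alone these lists had 5, 3 and 3 calls in all. Of these, 3 p53 targets were higher in males after gamma radiation. Polk had 0.43 ± 0.12, the apoptosis gene Bbc3 0.5 ± 0.15 and Zmat3 0.33 ± 0.11 (adjusted p = 0.159, 0.211 and 0.337). The sarcomere list (30 genes) had a smallest adjusted p of 0.0593, smooth muscle (16) 0.0518, Y-linked genes with Xist (5) 0.0661, skeletal muscle (11) 0.144, Schwann cells (10) 0.381, ion channels (23) 0.555 and adipocytes (9) 0.71. Apart from Prkdc no member of these 10 lists was called.

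The effects of the treatments were then compared with each other, as means of the sexes. Over 15879 genes the log2 changes on the Western diet and after gamma radiation had a covariance of 0.0145 and a correlation of 0.61, where unchanged groups set against the same sham libraries gave 0.00931 and 0.5 in 200 simulations. With permuted labels the upper 95% bound of the covariance was 0.017. For the Western diet and the mixed field the covariance was 0.0102 (simulated 0.00929) and the correlation 0.47 (simulated 0.5), and for the mixed field and gamma radiation 0.0099 (0.0093) and 0.48 (0.5). Over the 8439 genes of at least 10 CPM the covariance of the Western diet and gamma effects was 0.0078, above the bound of 0.0074, with a correlation of 0.72 (simulated 0.00331 and 0.5). The other 2 pairs had 0.00484 and 0.00383, below bounds of 0.00746 and 0.00736. With the sham libraries split between the effects, the mean covariance over 20 draws was 0.00586 for the Western diet and gamma (range 0.00288 to 0.0083), 0.0019 for the Western diet and the mixed field (-0.00428 to 0.00616) and 0.00133 for the mixed field and gamma (-0.0056 to 0.0061). Genes are not independent replicates in these values.

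Male and female sham libraries were compared last. The X-linked demethylases Kdm5c (-0.82 ± 0.09, adjusted p = 5.38e-11) and Kdm6a (-0.99 ± 0.12), which escape X inactivation, were lower in males. Lvrn (2.27 ± 0.28, adjusted p = 7.6e-09) and the complement component C7 (1.62 ± 0.26) were higher in males, and the collagen Col14a1 was lower (-1.21 ± 0.2); these 5 were chosen after their values were seen. Genes named by the fixed rule, which leaves out Xist, included atrial genes. Myl7 had 72.5 ± 72.4 CPM in males and 0.0368 ± 0.0414 CPM in females, and Sln, a calcium pump inhibitor of atrial muscle, 25.4 ± 25.8 and 0.0118 ± 0.025 CPM. Myl4 had 127 ± 128 and 2.17 ± 0.515 CPM, and Mybphl 12 ± 12.2 and 0.13 ± 0.158 CPM. Fgf12 was higher by 4.15 ± 0.93 (adjusted p = 0.00631). Tmem163 (3.91, adjusted p = 0.0357) and Cilp2 (3.3, adjusted p = 0.0402) lost their calls without any of 9 and 11 libraries, up to 0.0712 without male sham replicate 2 and 0.077 without male sham replicate 5. Bmp10 (5 ± 0.79) had 0.712 without male sham replicate 6.

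Between the sexes, 190 genes were called, 115 higher in males and 75 lower, with 1893 at an unadjusted p under 0.05. Within the runs 51 and 583 were called, and voom called 634. Without the libraries over 10 CPM of Myl7, which left 4 male sham libraries, 48 were called. Over 10 CPM lay 5 male sham libraries of the first run and 1 of the second, 5 and 0 male Western ones, 2 and 1 male mixed field ones, and 5 and 1 male gamma ones.

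**Figure D4:**
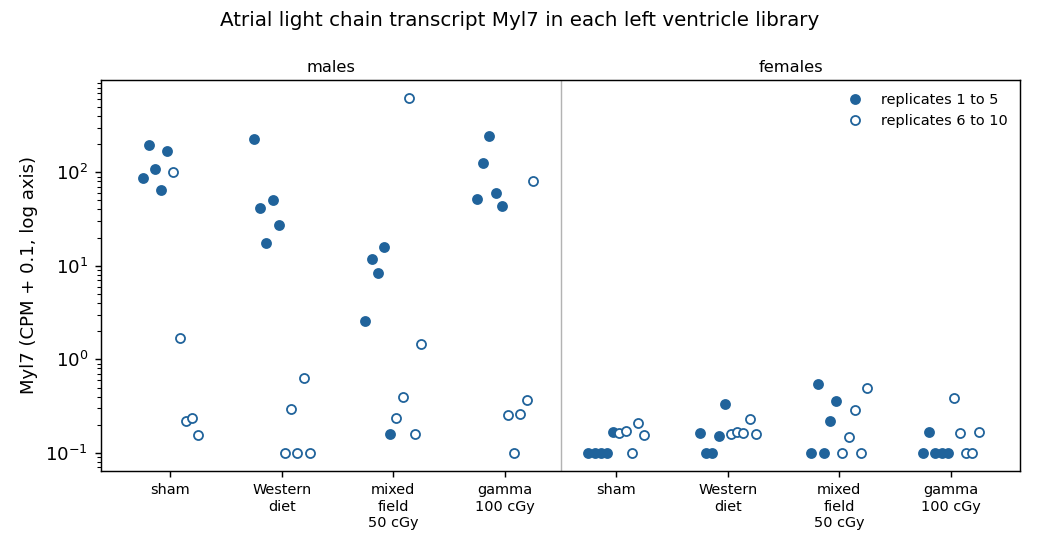
Level of Myl7 (CPM plus 0.1, log axis) in each library, by group; points are single libraries, marked by their run of title numbers. Male libraries reach 627 CPM, while no female library exceeds 0.452 CPM.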

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

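The tests chosen only after their result was seen were 2 further settings of the clock test, all tests on male gamma replicate 10, the correlation of the run effects between the sexes and the splits of the samples, within the runs too, while the clock, first-run, ribosomal RNA, thinning and GC tests were written before theirs.

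For 12 measures in each of 8 groups, the highest or lowest library was compared with its group of 10, and 19 of 96 lay apart. About 1 in 20 by chance is no guide, as genes already seen to stand out are included. Bmal1 was 7.85 CPM in male mixed field replicate 4, and Tspan4 was 20.6 CPM in male Western replicate 6. Serpinh1 was 147 CPM in male gamma replicate 10, and Bmp10 was 149 CPM in male sham replicate 6. Ms4a4b was 66.6 CPM in male gamma replicate 10, 3.94 in female mixed field replicate 5, 1.47 in male Western replicate 2 and 1.73 in male mixed field replicate 1. Myl7 was 627 CPM in male mixed field replicate 8, 228 in male Western replicate 1, 243 in male gamma replicate 3 and 0.286 in female gamma replicate 6. Xist was 280 CPM in female mixed field replicate 10 and 0.129 in female gamma replicate 7. Alas2 was 114 CPM in female mixed field replicate 5 and 42 in male Western replicate 7. S100a9, a neutrophil protein, was 22.5 CPM in male mixed field replicate 10, 18.4 in male Western replicate 7 and 4.87 in female gamma replicate 2.

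The interaction test found 71 genes whose Western diet effect differed between males and females, and 5 for the mixed field. For the Western diet the log2 difference, male minus female, was -4.96 for Bmp10, -3.17 for Spon2, -2.9 for Bmal1, 1.96 for Mthfd1l, -1.84 for Npas2, 1.75 for Per2, -1.53 for Tnfrsf12a and -1.5 for Tmem171. For the mixed field it was -2.65 for Spon2, -2.51 for Bmal1, -1.01 for St6galnac3, 0.86 for Tspan4 and -0.79 for Leo1.

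The first pattern is the 63 genes called for the Western diet in males. Of 60 outside the clock list, 51 (85%) changed with the sign of their slope on a clock index within the female groups. A run term was used, and terms for each run of each group and ribosomal RNA also gave 51. In 2000 random sets matched on expression the median was 58.3%, with 95% between 45 and 70%. The sets were not matched on correlation between genes, so 85% does not single out the clock. Of the 452 genes called in the first run alone 67.7% had the same direction in the second (66.8% by group means, which 6.75% of all assignments of the second-run libraries reached), with a median change of 0.06 toward the first run's direction against 0.61 in the first, so preparation that differed between the groups in the first run only cannot be told apart. With ribosomal RNA share and run terms for each sex 16 of the 63 stayed past the threshold. The median absolute change of the 63 went from 0.48 to 0.39, so preparation marked by that share cannot be told apart. A difference of clock phase between the groups is a hypothesis for part of this pattern. Whether the diet moved the clock or tissue was collected at other hours stays open, as no hour is given.

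The second pattern is the lymphocyte genes called for gamma radiation in males. Without male gamma replicate 10 only 1 gene was called, so lymphocytes in that library may account for the others. B cell markers argue against lymph node or blood holding both T and B cells as the source. Their median log2 ratio to the other male libraries was -0.25, against 3.75 for T and natural killer cell markers. Yet 10 of 11 erythroid markers (median 0.92) and 25 of 27 macrophage markers (median 0.6) lay above. Of that library's 178 T cell receptor beta variable counts, 150 lay on Trbv19 (84.3%, 95% Clopper-Pearson interval 78.1 to 89.3%, counting error only). An expanded T cell clone could give this, also in blood or node. Whether radiation had a part in it stays open with 1 library.

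The third pattern is the shift between title numbers 1 to 20 and 21 to 40, which took in 4359 genes in males and 3899 in females. Depth is argued against, since at least 88.6% of these stayed called after thinning to the smallest total, and GC content with exon length explained at most 5.07% of the variance. A single shift shared by both sexes is argued against by a correlation over genes of 0.04, where genes are not independent replicates. Separate handling of the male and female libraries in each run may account for it, but the labels name no batch and this was not tested.

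Other splits of the samples were drawn for each count, 100 per comparison with the real one included. A random assignment of single libraries is argued against for the Western diet in males. There 1 split, the real one, gave the 63 genes and the highest other gave 2, but leaving out 1 library gave 20 to 195. Each group was made of 2 blocks of 5 consecutive title numbers, which the drawn splits break up, within the runs too. A difference between such blocks is therefore not excluded for any count. Such an assignment is also argued against for the difference between the sexes in the diet effect (1 split, 71 genes, highest other 43). The same holds for males against females in sham (1 split, 190 genes, highest other 176). Leaving out 1 library gave 40 to 111 and 144 to 245, so the lowest of each range lay below the highest other split. A random assignment is argued against only weakly for the mixed field in males (4 splits gave 11 or more) and the Western diet in females (4 splits gave 3 or more). The highest others there were 571 and 464, far above the real count, which points to a structure of the samples. Among 14 counts tested, these 2 fell to 4 without male sham replicate 1 and to 0 by edgeR (803 unadjusted) without female sham replicate 9. Chance cannot be excluded for gamma radiation in males (20 splits, 28 genes, highest other 368), the mixed field against gamma radiation (12 splits, 3 genes, highest other 408) or the difference between the sexes in the mixed field effect (5 splits, 5 genes, highest other 136). These splits ignore the runs. Drawn within the runs, 1 split of 100 reached the Western count in males (highest other 3), 1 its difference between the sexes (54) and 1 the sexes in sham (4). In such splits 3 reached the mixed field count in males (20), 3 the Western count in females (12), 13 the gamma count in males (58), 11 the mixed field against gamma (329) and 2 the difference between the sexes in the mixed field effect (6). For the 6 counts of 0 by edgeR every split gives at least 0, so that 100 of 100 reached them was fixed and says nothing about chance. Their highest others were 467 for the mixed field and 712 for gamma radiation in females, 1, 400 and 49 for the Western diet, mixed field and gamma means, and 4 for the difference between the sexes in the gamma effect. The split that follows the runs called 1807 genes for the Western diet, 1159 for the mixed field and 1652 for gamma radiation in males, and 1069, 971 and 498 in females.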

How the results depend on the processing

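The fits with a run term for each sex, without libraries over 10 CPM of Myl7, with clock components, without 4 libraries, with ribosomal RNA share and run terms for each sex, leaving out each library and the replicate block for the sex differences were chosen only after the results were seen. Of 339 gene values followed, 76 passed the threshold, and 60 of these stayed past it with DESeq2, 74 with RLE, 67 with no filter, 75 with a run term, 43 without the 4 libraries, 41 with ribosomal RNA share and run terms, 21 with clock components and 5 without libraries over 10 CPM of Myl7, which left 4 sham, 5 Western, 7 mixed field and 4 gamma males. Except for fewer libraries in some fits, the cause of each change was not tested. Depth limits genes near 1 CPM.

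The values here are counts of called genes, where a treatment named without a sex stands for the mean of the sexes. DESeq2 gave Western males 146, mixed field males 23, gamma males 12, Western females 8, gamma females 3, the Western sex difference 110, the mixed field sex difference 11, the gamma sex difference 2, mixed field against gamma 7. No filter gave Western males 32, gamma males 45, the Western sex difference 47, mixed field against gamma 5, and the stricter one gamma males 13. Voom gave Western males 460, gamma males 0, Western females 0, gamma females 3, the mixed field mean 4, the gamma mean 42, the Western sex difference 140, the mixed field sex difference 38, mixed field against gamma 0, the sexes in sham 634. The run term gave Western males 124, mixed field males 18, mixed field against gamma 6. Surrogate variables gave Western males 290, mixed field males 26, gamma males 0 (1223 unadjusted by edgeR), Western females 7, the Western sex difference 292, the mixed field sex difference 9, mixed field against gamma 43, the sexes in sham 1005. Only the groups compared gave mixed field males 7, gamma males 0 (844 unadjusted), Western females 5, the gamma mean 1, mixed field against gamma 1. Without the library that stands apart the mixed field sex difference was 3 and mixed field against gamma 1. Title numbers 1 to 20 gave Western males 452, mixed field males 17, gamma males 0, Western females 1, mixed field females 39, gamma females 6, the Western mean 92, the mixed field mean 48, the gamma mean 7, the Western sex difference 22, the mixed field sex difference 9, the sexes in sham 51, and 21 to 40 gave Western males 0, mixed field males 0, gamma males 7, mixed field females 4, the Western sex difference 26, the mixed field sex difference 0, mixed field against gamma 24, the sexes in sham 583. A run term for each sex gave Western males 194, mixed field males 25, gamma males 16, Western females 28, gamma females 4, the gamma mean 2, the Western sex difference 154, the mixed field sex difference 19, mixed field against gamma 12. It gave the sexes in sham 414, of which 118 were among the 190 reported. With run terms for each sex that contrast is the difference fitted for the first run only, so it is not the same quantity. The same holds for the sexes in sham with ribosomal RNA share and run terms. Without libraries over 10 CPM of Myl7 the counts were Western males 0, mixed field males 0, gamma males 0, the Western sex difference 1, the mixed field sex difference 3, mixed field against gamma 0, the sexes in sham 48. Clock components gave Western males 0, mixed field males 0, Western females 0, the Western sex difference 1, the mixed field sex difference 0, mixed field against gamma 33. Without the 4 libraries mixed field males was 3 and gamma males 0. Ribosomal RNA share and run terms gave Western males 20, mixed field males 20, gamma males 0 (791 unadjusted), Western females 37, gamma females 9, the gamma mean 1, the mixed field sex difference 8, mixed field against gamma 43.

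Leaving out 1 library gave Western males 20 to 195, mixed field males 4 to 28, gamma males 1 to 48, Western females 0 to 11, mixed field females 0 to 0, gamma females 0 to 2, the Western mean 0 to 0, the mixed field mean 0 to 4, the gamma mean 0 to 0, the Western sex difference 40 to 111, the mixed field sex difference 3 to 12, the gamma sex difference 0 to 2, mixed field against gamma 0 to 8 and the sexes in sham 144 to 245. Title numbers do not pair the samples: in sham, deviations of the 10 same-numbered pairs correlated at -0.14 to 0.115, with 3 over 0.1. The replicate block gave 135 for male against female, sham on the normal diet, the Western sex difference 42, the mixed field sex difference 2 and the gamma sex difference 0. Of 79 list calls in 432 tests, 2 held with an estimated correlation, 3 with fry's directional test and 0 with its mixed test; 123 passed with clock components. Covariances of the Western and mixed field, Western and gamma, and mixed field and gamma means were 0.00484, 0.0078 and 0.00383 over genes of at least 10 CPM, and 0.0019, 0.00586 and 0.00133 with sham split.

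These log2 values reversed. Bmp10 was 0.6 in Western males, 0.89 in mixed field males, 0.62 in gamma males, 0.27 in the Western sex difference, 0.51 in the gamma sex difference and -0.13 in the sexes in sham without libraries over 10 CPM of Myl7; 0.94, 1.26, 0.79, 0.6, 0.69 and -0.54 without the 4 libraries; and with DESeq2 1.22 in mixed field males, 0.88 in gamma males, 0.56 in the Western sex difference, 0.77 in the gamma sex difference and -0.49 in the sexes in sham. With DESeq2 Tcf7 was -0.02 in gamma males. Without libraries over 10 CPM of Myl7 Fmod was 0.08 in mixed field males, in gamma males Cox5a was 0.07, Ndufa9 0.06, Ndufa10 0.01, mt-Nd1 0.03, mt-Nd2 0.09, Fcgr1 -0.11 and Lck -0.15, and in the sexes in sham Tmem163 was -0.84 and Cilp2 -0.71. With clock components Col6a2 was 0.01 in mixed field males, Pdk2 0.05 in Western females, Nppb -0.09, Rcan1 -0.02, S100a8 -0.22 and Retnlg -0.9 in mixed field females, Acta1 0.01 in the mixed field mean and Tnfrsf12a 0.19 in the Western sex difference.

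These list calls had the opposite sign, with the adjusted p given, and of them 0.00116 and 0.00131 passed in the new direction. With clock components the clock had 0.72 in Western males, 0.431 in mixed field males, 0.305 in Western females, 0.901 in mixed field females, 0.194 in the gamma mean, 0.398 in the Western sex difference and 0.548 in the mixed field sex difference, fibrosis 0.108 in mixed field males, 0.64 in the mixed field mean and 0.0727 in the mixed field sex difference, and endothelium 0.875 in the mixed field sex difference. In title numbers 21 to 40 atrial markers had 0.443 in mixed field males, glycolysis 0.693 and the mitochondrially encoded chain 0.999 in gamma males, fatty acid oxidation 0.614 and the nuclear chain 0.00116 in mixed field females, fatty acid oxidation 0.867 and hypertrophy 0.772 in the mixed field mean, and the mitochondrially encoded chain 0.483 in the gamma sex difference. In title numbers 1 to 20 fatty acid synthesis had 0.914 and fibrosis 0.00131 in the mixed field mean, and the nuclear chain 0.901 in the gamma sex difference.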

Other observations

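The genes that differed between the title-number runs were described after their values were seen, the list counts between the runs were not planned, and the test on the library without Xist was written before its result was seen.

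In males, libraries of the second run had higher levels of Med12, a subunit of the Mediator complex (0.8 on the log2 scale), and of the splicing-related genes Srrm2 (0.79) and Pnisr (0.96). Of the fatty acid oxidation list 16 of 32 genes were lower in that run, and of the fibroblast list 11 of 20, with a median of -0.35. In females, the second run had lower levels of the nuclear RNA Malat1 (-1.91), the giant sarcomere gene Ttn (-1.07), Lars2 (-1.9) and the ribosomal RNA gene Rn18s-rs5 (-2.52). There 25 of 49 interferon genes were higher, with a median of 0.28, as were 8 of 13 mitochondrially encoded chain genes, with a median of 0.36. Of the clock list 10 were higher and 3 lower.

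In male gamma replicate 10, Cd4, the coreceptor of helper T cells, had 13.9 CPM, against a median of 0.944 CPM in the other male libraries. Cd8a, the coreceptor of cytotoxic T cells, had 0.545 CPM, and the B cell gene Cd79a had 0.0908 CPM. Of 144 counts on T cell receptor alpha variable segments, 78 lay on Trav6-4 and 63 on Trav9-1.

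Female gamma replicate 7, with 0.129 CPM of Xist, had a mean log2 CPM of 5.43 over 4 genes that escape X inactivation (Kdm5c, Kdm6a, Eif2s3x and Ddx3x). The other 39 female libraries had 6.03 ± 0.27 (SD) with a lowest value of 5.21, and the 40 male libraries 5.28 ± 0.17. A single X chromosome in most cells of that library may account for the missing Xist, but this cannot be told apart from other causes, because another female library lay lower. It had 0 CPM of Ddx3y, Kdm5d, Uty and Eif2s3y, so its counts hold no Y-linked transcript of these 4. Against means in the other females and in males, Kdm5c was 45.8 CPM there (76.4 and 42.8), Kdm6a 12.6 CPM (22 and 12), Eif2s3x 39.8 CPM (59.4 and 33.2) and Ddx3x 149 CPM (198 and 137).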
